A study of Mus musculus with 12 samples.

How the data were processed

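RNA was sequenced from 12 mouse samples in 4 groups of 3. The sorted groups were Sertoli cells isolated by flow cytometry from testes of control mice (Amh-Cre, Ptbp1 flox/wt, mTmG) and of conditional knockout (cKO) mice with both Ptbp1 alleles floxed. Per the labels, their poly(A) RNA came from 100 ng of total RNA and was made into NEBNext Ultra Directional libraries. The cultured groups were wild-type Sertoli cells in primary culture, sequenced as input total RNA and as RNA recovered with PTBP1 by immunoprecipitation, both with the NEBNext Ultra II Directional kit. The labels give no animal age and no immunoprecipitation with a control antibody. They do not say whether the samples of a group came from separate animals or cultures, so p-values here measure the spread between these samples, which may be technical. The names of the cultured libraries hold 2 numbers, 1 and 1, 1 and 2, and 2 and 1 for libraries 1, 2 and 3 of the inputs and of the immunoprecipitates, and the labels do not say what they mean; if the first marks a culture, n = 3 there holds 2 cultures.

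The authors deposited 1 table of the sorted libraries and 1 of the cultured libraries. Both hold counts: in the deposited tables each value used here is a whole number of reads per gene, with no normalization. The submitters' processing notes name bcl2fastq 2.20, cutadapt, Bowtie2 2.3.5.1, STAR, HTSeq, DESeq2 and genome build mm10, without saying which step or table each was used for. The sorted table also holds an exon length per gene and gene positions counted from 0, given here counted from 1. It further holds the authors' own test, with a p-value per gene, unadjusted and adjusted, and a signed fold change in which a fall is written as minus the inverse ratio. The second sheet of the workbook repeats the first in another order, and 84 columns of other per-library values were not used here. Those of all exon, unique exon, intron and junction reads were examined during this work and then set aside with every result from them, because the columns name a group but no sample and only 1 measure per library was kept. Library columns of the sorted table name the group but no replicate number, so libraries are numbered by their order in the table.

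Counts were tested with edgeR 4.0.16 in R 4.3.3. Each comparison was fitted on its own 6 libraries, after filterByExpr and TMM scaling, by the robust quasi-likelihood fit and its two-sided test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Levels are CPM, counts divided by the TMM-scaled library size, given as mean ± SD of the 3 libraries of a group, and standard errors of a log2 fold are its size divided by the root of the test's F. An enriched transcript had an adjusted p under 0.05 and a log2 fold of 1 or more over input. The overlap of enriched transcripts with genes changed in the cKO was tested by Fisher's exact test, two-sided, over the genes tested in both comparisons. For gene lists, camera of limma 3.58.1 was run on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over all lists with 5 or more tested members. The 36 lists had 1007 distinct members, of which 1040 of 1043 memberships were matched in the sorted table and 997 in the cultured table. They cover the PTBP family, reported PTBP1 splicing targets, Sertoli cell markers, the cytoskeleton and junctions, mTOR, protein kinase C, metabolism, stress, the cell cycle, splicing regulators, ribosomal proteins, histones, mitochondrial genes and markers of other testis cells.

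Genes were named by a rule. It took 13 genes whatever their values: Ptbp1, Ptbp2, Ptbp3, Prkca, Mtor, Rptor, Rictor, Amh, Sox9, Wt1, Vim, Gja1 and Cldn11. It added the 10 largest rises and the 10 largest falls past the threshold with a mean log2 CPM of 3 or more and no overlap between the groups, leaving out predicted and unnamed genes. It also added up to 4 members of each list with the smallest p, and for the overlap the 10 genes per direction with the smallest p in the cKO. Some genes named by this rule and 1 list, which was tested and adjusted with the others but is left out of the text and figure, are not reported here. The comparisons, tests, lists, named-gene rule and the alternatives listed first below were set before the data were examined.

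Total counts ran from 11980474 to 13750181 in the sorted libraries, from 12894035 to 15315115 in the inputs and from 26725003 to 28796396 in the immunoprecipitates. On data simulated from the sorted counts with 200 changed genes, 49.2% of 1.5-fold, 80.3% of 2-fold and 96.7% of 4-fold changes were recovered. On data simulated from the cultured counts the shares were 90.8%, 98.5% and 100%. Far fewer genes were changed in these simulations than were called in the data, so the shares may not hold for the comparisons themselves. No pair of libraries within a group was a duplicate: the smallest ratio of chi-square to its degrees of freedom between any 2 of them was 2.13, where 1 is sampling noise. Libraries 1 and 2 of the cultured groups, whose names share the first number, were closer to each other (2.13 in the inputs and 3.41 in the immunoprecipitates) than to library 3 (3.03 and 3.11, and 8.40 and 5.58).

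The alternatives set beforehand were DESeq2 1.42.0, its size factors, library size alone, no filter, a filter of 1 CPM in 3 libraries, added thresholds of 1.5-fold and 2-fold, a block by replicate number or by the first number of the library name, other definitions of enrichment, covariates in the overlap, camera with an estimated correlation, fry, and leaving out each library. Alternatives chosen after seeing the data were leaving out mitochondrially encoded genes, leaving out the third library of both sorted groups, and leaving out ribosomal protein and histone genes with Ccnb1ip1. Sequence-based measures such as GC content and pyrimidine tracts were not analysed here because no genome sequence was at hand. Splicing was not tested: the counts used are reads per gene, and the exon, intron and junction reads of the sorted table were set aside.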

Results

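Sertoli cells are the somatic nurse cells of the seminiferous tubule, and PTBP1 (polypyrimidine tract binding protein 1) is an RNA-binding protein that regulates splicing and other steps of RNA metabolism. RNA of 12 mouse samples was sequenced in 4 groups of 3. Sorted Sertoli cells came from control mice, which carried 1 floxed Ptbp1 allele, and from conditional knockout (cKO) mice, which carried 2, both with a Cre driven from the Amh promoter. Cultured wild-type Sertoli cells gave an input and a PTBP1 immunoprecipitate. The series title names cytoskeletal organization, an mTOR and PKCα pathway and spermatogenesis as its subjects. The 3 control libraries held 13503686, 12813037 and 12888737 counts, and the 3 cKO libraries held 13750181, 11980474 and 13630761. The inputs held 12894035, 14946009 and 15315115, and the immunoprecipitates 28796396, 27647718 and 26725003. The first principal component of the sorted libraries held 53.7% of the variance and parted cKO from control. On the second, with 18.2%, the third control library (-25.18) and the third cKO library (-28.31) stood apart from the others of their groups.

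The comparison of sorted cKO with control cells asked which transcripts differ when Sertoli cells lose Ptbp1. Ptbp1 itself fell by 4.99 on the log2 scale, from 247 ± 5.29 to 7.78 ± 0.184 CPM (mean ± SD, n = 3 libraries per group; adjusted p = 4.57e-10). Its paralogs Ptbp2 and Ptbp3, which bind similar pyrimidine-rich RNA, rose by 1.41 and 0.37. The meiotic genes Sycp1, Sycp2 and Sycp3, which encode parts of the scaffold that pairs chromosomes, rose by 1.97, 1.76 and 1.84. Amh (anti-Müllerian hormone) and Dhh (desert hedgehog), which Sertoli cells secrete, fell by 1.09 and 1.02. Of 40 splicing regulator genes 29 rose, while 15 of 25 genes of glycolysis and 16 of 26 of the lysosome fell.

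In all, 2359 genes were higher and 2870 lower of 13405 tested (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median size of change among them was 0.65 on the log2 scale, and 550 genes rose and 310 fell by 2-fold or more. The groups did not overlap for 49.7% of tested genes, where chance gives 10%. These directions are relative: scaling by library size alone moved the median log2 fold of all genes by 0.17 and gave 3476 higher and 1863 lower. Without the third library of both groups, 3023 genes were higher and 3545 lower.

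Ptbp1 lies on chromosome 10 of mm10 from 79854427 to 79864771, and its level was 31.7 times lower in the cKO. Ptbp2 rose from 37.7 ± 4.40 to 100 ± 5.85 CPM (n = 3; adjusted p = 4.16e-05). Ptbp3 rose from 75.7 ± 9.30 to 98.0 ± 7.35 CPM (n = 3; adjusted p = 0.0270), and its call was lost without the second control library (adjusted p = 0.0631), the third control library (0.0884), the first cKO library (0.0934) or the second cKO library (0.0824).

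**Figure D1:**
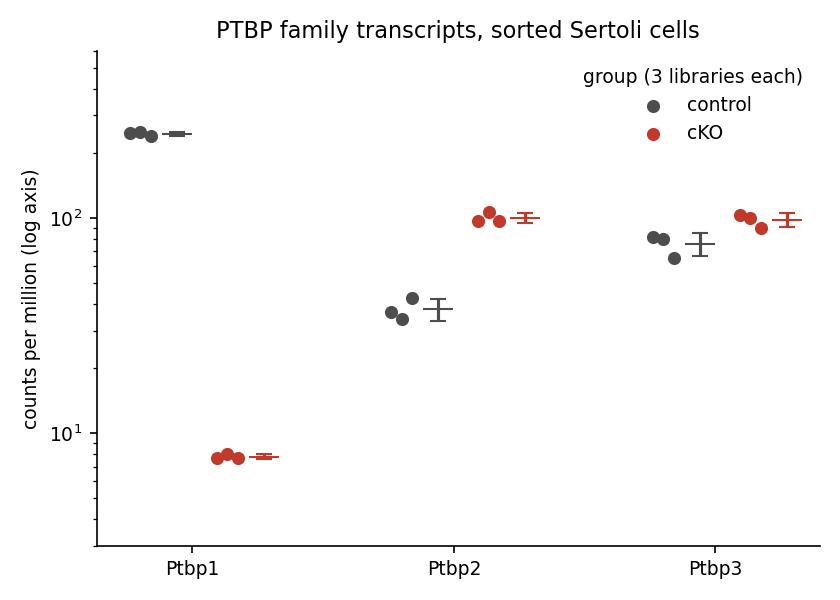
Levels of Ptbp1, Ptbp2 and Ptbp3 in the sorted libraries, in CPM on a log axis; points are the 3 libraries of a group and bars the mean with its SD. Ptbp1 fell from a mean of 247 to 7.78, while Ptbp2 rose from 37.7 to 100.

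The largest rises of genes at or above the named-gene level were Adamts1, a secreted metalloproteinase, by 2.81 (from 8.83 ± 2.003 to 61.9 ± 35.4 CPM, n = 3), Cadps, a factor for vesicle exocytosis, by 2.53, Nes (nestin) by 2.29 and Actn1 (alpha-actinin 1) by 2.10. Sycp1, Ccn1, Epha2, Sycp3, Tnfrsf12a and Creb5 rose by 1.97, 1.89, 1.88, 1.84, 1.82 and 1.79. After Ptbp1, the largest falls included Wnt6 by 2.90 (from 16.5 ± 2.16 to 2.196 ± 0.2504 CPM, n = 3), Scn8a, a sodium channel, by 2.17 and Olig1, a transcription factor, by 2.11. Tmie, Reln and Castor1 fell by 1.958, 1.77 and 1.61. The third cKO library held much of 4 of these rises. Without it the log2 fold was 1.42 for Nes, 1.08 for Actn1, 1.26 for Ccn1 and 0.99 for Epha2, which then lost its call (adjusted p = 0.0791). Tnfrsf12a (77.88 CPM, against 33.55 and 35.64 in the other cKO libraries), Creb5 (20.68 against 7.425 and 14.18) and Adamts1 (96.24 against 25.5 and 63.91) were also highest in that library. Some blood and vascular markers were also highest in that library: Hbb-bs (23.75 CPM, against 0.8406 and 2.271 in the other cKO libraries), Hba-a2 (13.65 against 1.401 and 1.175) and Cdh5 (4.846 against 0.7005 and 1.175). Alas2, of the red blood cell list, was lowest there (8.191 against 20.8 and 16.37). In controls Alas2 was at 42.8 CPM and Hbb-bs and Hba-a2 at 2.31 and 2.70, so Alas2 did not follow these 2 genes. With no filter on low counts Nes, Actn1, Ccn1 and Epha2, at log2 folds of 2.28, 2.10, 1.90 and 1.88, lost their calls (adjusted p of 0.107, 0.163, 0.0898 and 0.211). Nes also lost it without the third control library (adjusted p = 0.0576), and Actn1 and Epha2 without the first (0.0660 and 0.0824) or the third (0.0563 and 0.0938). Without the third library of both groups Adamts1 and Ccn1, at log2 folds of 2.38 and 1.49, lost theirs (adjusted p of 0.0943 and 0.0515).

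Of 30 tested Sertoli cell markers, 1 rose, 16 fell and 13 did not pass (4 rose and 13 fell with library size alone). Amh fell from 268 ± 13.1 to 126 ± 17.6 CPM (n = 3; adjusted p = 9.71e-05), Nr5a1, a steroidogenic transcription factor, by 0.96, and Trf (transferrin) by 1.02. Sox9, the transcription factor that sets Sertoli cell fate, fell by 0.38 and the junction gene Cldn11 by 0.36, and both lost the call with library size alone (adjusted p of 0.0997 and 0.146). The call of Sox9 was also lost without the first or second control library (0.0643 and 0.0626), and that of Cldn11 without those (0.0501 and 0.0760) or the second cKO library (0.0694). Wt1 was at 609 ± 52.9 CPM in controls and 583 ± 20.5 in the cKO (n = 3; adjusted p = 0.673). The list was called lower by camera (median log2 fold -0.37, adjusted p = 0.00188), but not with an estimated correlation (adjusted p = 0.522). Among paracrine factors for germ cells, 2 of 16 rose and 5 fell, including Inha by 0.73, and the list was not called (adjusted p = 0.611).

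The mTOR list, which covers the growth-controlling kinase complexes and their regulators, had 8 of 57 members higher and 17 lower and was not called (adjusted p = 0.264). Rptor, the scaffold of mTOR complex 1, fell from 131 ± 16.9 to 79.2 ± 8.16 CPM (n = 3; adjusted p = 9.72e-04). Castor1, an arginine sensor of that complex, fell by 1.61, the lysosomal transcription factor Tfeb by 1.21 and Akt1s1 by 0.94, and the translational repressor Eif4ebp2 fell to 0.501 of its control level. Mtor itself had a log2 fold of -0.19 (adjusted p = 0.279) and Rictor, of complex 2, 0.26 (adjusted p = 0.264), which passed without the third cKO library (log2 fold 0.45, adjusted p = 0.0152) and without the third library of both groups (0.31, 0.00730). Prkca, which encodes PKCα, was at 13.6 ± 5.099 CPM in controls and 11.5 ± 3.22 in the cKO (n = 3; log2 fold -0.24, adjusted p = 0.516). Of 17 protein kinase C and related genes 2 rose and 5 fell: the related kinase Prkd1 fell by 0.68, the PKC anchor Rack1 by 0.71, and Pkn2 rose by 0.68. That list was not called (adjusted p = 0.264).

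Cytoskeletal genes moved in both directions. In the microtubule list 6 of 45 members rose and 18 fell, among them the tubulins Tuba1b by 1.27, Tuba1a by 1.13, Tubb3 by 1.03 and Tubb5 by 1.01. In the actin list 10 of 69 rose and 18 fell: the Arp2/3 subunits Arpc4 and Actr2 went opposite ways, by -0.94 and 0.76, the myosin light chain Myl9 fell by 0.75, and the actin-severing factor Cfl2 rose by 0.91. Intermediate filaments had 3 of 13 higher and 3 lower (3 and 1 with library size alone): Nes, Lmnb1 and Dst rose by 2.29, 0.46 and 0.45, and Vim (vimentin) fell from 1691 ± 94.6 to 1091 ± 116 CPM (n = 3; adjusted p = 0.00135). The call of Dst was lost without the second or the third control library (adjusted p of 0.0909 and 0.0574) or the second cKO library (0.0654). Of 33 genes of the blood-testis barrier and cell junctions 4 rose and 4 fell: Cxadr, a junctional adhesion receptor, rose by 1.58, the polarity gene Mpp5 by 0.92, and Nectin2 fell by 0.93. Gja1 (connexin 43) had a log2 fold of 0.11 (adjusted p = 0.586). These lists were not called, with adjusted p of 0.264 for microtubules, 0.341 for actin, 0.714 for intermediate filaments and 0.931 for junctions. With library size alone the median turned from negative to positive in the microtubule (12 higher and 12 lower), actin (16 and 14), junction (7 and 1) and mTOR (12 and 11) lists, and with DESeq2's size factors in the microtubule and junction lists.

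The list with the smallest camera p was that of spliceosome and other splicing regulators, of which 29 of 40 rose and 1 fell (31 and 1 adjusted over the list alone). Srsf10, Hnrnph1, Srsf5 and Srsf7 rose by 0.94, 0.88, 0.84 and 0.71. The median log2 fold was 0.47 (adjusted p = 3.59e-06, and 0.522 with an estimated correlation). Of 13 reported PTBP1 splicing targets 4 rose and 3 fell (6 and 3 adjusted over the list alone), with no call (adjusted p = 0.802). Ptbp2, Ptbp3 and Actn1 rose, Src and Pkm fell by 0.50 and 0.75, and the other that fell is the deleted Ptbp1 itself. Of 4 tested nuclear long non-coding RNAs Malat1 and Neat1 rose by 0.80 and 0.59 and Gm26917 fell by 1.13. The call of Neat1 was lost without the second or the third control library (adjusted p of 0.0625 and 0.0670) or the first cKO library (0.0575), or without the third library of both groups (0.0514). Gm26917 lost its call with no filter on low counts (adjusted p = 0.0812).

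Of the lists of metabolism and stress, camera called those of glycolysis, the lysosome and the integrated stress response lower, and none of these with an estimated correlation. In glycolysis and lactate export 0 of 25 rose and 15 fell (1 and 15 adjusted over the list alone, 2 and 12 with library size alone). Those that fell included the hexose transporter Slc2a8 by 1.08, the lactate exporter Slc16a3 by 0.97, its partner Bsg by 0.75 and Pkm (pyruvate kinase) by 0.75. The list median was -0.48 (adjusted p = 5.10e-04, and 0.522 with an estimated correlation). In the lysosome and phagocytosis list 0 of 26 rose and 16 fell (1 and 16 adjusted over the list alone, 3 and 12 with library size alone). The phagocytic receptor Axl fell by 0.92, the lysosomal enzyme Hexa by 0.83, and Scarb1 by 0.63. Its median was -0.46 (adjusted p = 0.00230, and 0.522 with an estimated correlation). The integrated stress response list, which holds targets of amino acid stress signalling, had 1 of 18 higher and 9 lower (median -0.43, adjusted p = 0.0280, and 0.876 with an estimated correlation). With library size alone 2 were higher and 7 lower. The amino acid transporter subunits Slc7a5 and Slc3a2 fell by 1.18 and 0.86 and the biosynthetic enzymes Asns and Phgdh by 0.90 each. That call was lost without the second control library (adjusted p = 0.0575), the first cKO library (0.257) or the second cKO library (0.0562). Of 22 genes of cholesterol synthesis and uptake 10 rose and 3 fell (11 and 0 with library size alone; list adjusted p = 0.264): Idi1, Stard4, Sc5d and Hmgcs1 rose by 1.57, 1.02, 1.004 and 0.71. Of 14 retinoic acid genes 1 rose and 6 fell (1 and 3 with library size alone; list adjusted p = 0.210), including the degrading enzyme Cyp26b1 by 1.30 and the receptors Rara and Rxrb by 0.98 and 0.84.

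Among markers of other cells in the testis, the spermatocyte list rose: 11 of 26 members were higher and 2 lower (13 and 2 adjusted over the list alone, 13 and 0 with library size alone), with a median of 0.83 (adjusted p = 1.17e-04, and 0.522 with an estimated correlation). Sycp1 rose from 15.9 ± 2.03 to 62.1 ± 2.41 CPM (n = 3; adjusted p = 1.90e-05), and Smc1b, a meiotic cohesin subunit, from 10.98 ± 1.015 to 35.16 ± 4.045. The abundant spermatocyte transcript Ldhc was at 174 ± 63.2 CPM in controls and 211 ± 15.2 in the cKO (n = 3; adjusted p = 0.292), and Rec8, another meiotic cohesin subunit, fell by 0.41. Of 17 spermatogonia genes 3 rose and 1 fell (3 and 0 adjusted over the list alone; list adjusted p = 0.208): the germ cell RNA-binding genes Dazl and Ddx4 rose by 1.39 and 0.72 and Tex101 by 0.46, and Uchl1 fell by 0.38. The call of Tex101 was lost without the first or the third control library (adjusted p of 0.0715 and 0.0624) or the third cKO library (0.0608), or without the third library of both groups (0.0800). That of Uchl1 was lost without any of the first or second control or cKO libraries (adjusted p from 0.136 to 0.232), with DESeq2's size factors (0.0693), with library size alone (0.261) or without mitochondrially encoded genes (0.0832). Of 17 spermatid genes 0 rose and 0 fell by edgeR, 0 of them at an unadjusted p under 0.05 (list adjusted p = 0.931).

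**Figure D2:**
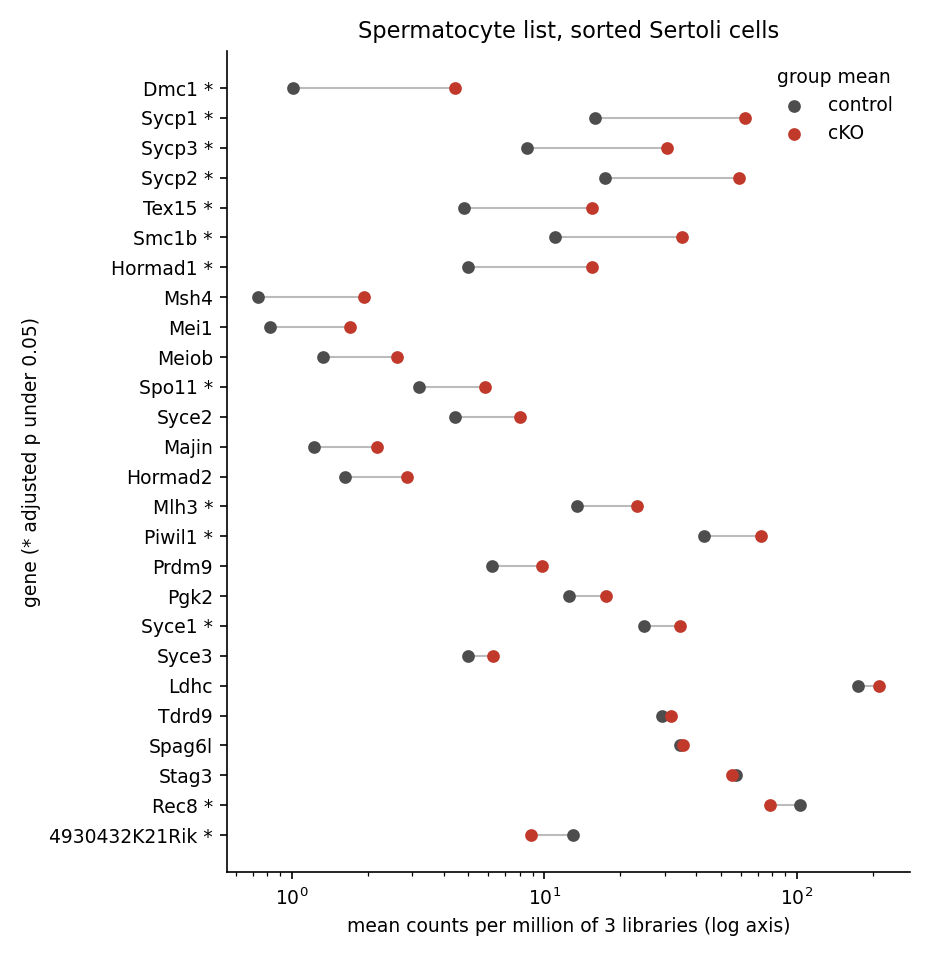
Mean level of the 26 tested genes of the spermatocyte list in control and cKO sorted cells, in CPM on a log axis, with called genes starred. Of these, 11 were higher in the cKO, such as Sycp1 (15.9 to 62.1), and Rec8 was lower (103 to 77.9).

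Of 7 Leydig cell genes the steroidogenic genes Star and Fdx1 rose by 0.62 and 0.52 and Pdgfra fell by 0.59, a call lost without any of the 6 libraries but the third control library (adjusted p from 0.0814 to 0.234), and with DESeq2 (0.0574), its size factors (0.0606), library size alone (0.145) or without mitochondrially encoded genes (0.0743). Of 9 peritubular myoid genes 1 rose and 1 fell, Myl9 by 0.75. The riser was Tagln by 1.71, whose call was lost without the first or second control library (adjusted p of 0.105 and 0.0737) or the third cKO library (log2 fold 1.07, adjusted p = 0.165), or without the third library of both groups (0.0565). None of 4 macrophage and 8 endothelial genes passed by edgeR, 0 of each at an unadjusted p under 0.05; without the third library of both groups Mrc1 (log2 fold 0.25, adjusted p = 0.0261) and Eng (-1.47 against -0.37, adjusted p = 0.0285) passed. Of 5 red blood cell genes 1 fell, Alas2 by 1.503, a call lost with no filter on low counts (adjusted p = 0.117). The median log2 folds were 1.01 for the red blood cell list, the highest of any tested list, with Hbb-bs at 1.961 (adjusted p = 0.201) and Hba-a2 at 1.01 (0.379), and 0.42 for the macrophage genes, which were too few for camera. In the granulosa list 1 of 6 rose, Lef1 by 0.79, which lost its call without the first or second control library (adjusted p of 0.0509 and 0.0742) or the third cKO library (0.0656). Of 8 neuronal genes Nrxn3, at 0.321 ± 0.284 CPM in controls and 2.196 ± 0.412 in the cKO (n = 3; adjusted p = 0.00397), rose by 2.73 (3.69 without the first control library), and Tubb3 fell by 1.03. The tested lists of this paragraph were not called, with adjusted p of 0.427 for Leydig cells, 0.966 for myoid cells, 0.931 for endothelium, 0.932 for red blood cells, 0.359 for granulosa genes and 0.490 for neuronal genes.

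The lists of cell state gave no call. Of 25 cell cycle genes 7 rose and 1 fell (adjusted p = 0.264), with Bub1, Top2a and Pcna up by 1.09, 0.89 and 0.68. Without the third control library that list was called higher (adjusted p = 0.0340), though with all libraries its adjusted p was 0.940 with an estimated correlation. The p53 and apoptosis list had 5 of 20 higher and 4 lower (6 and 2 with library size alone; list adjusted p = 0.802): Sesn2 and Bcl2l1 fell by 0.87 and 0.78. Of 24 stress and immediate early genes 6 rose and 5 fell (6 and 2 with library size alone; list adjusted p = 0.931), with Hsp90aa1 and Klf6 up by 1.03 and 0.64 and Zfp36 down by -0.62, a call lost without the second control library (adjusted p = 0.0545). The interferon list had 1 of 14 higher, B2m by 0.98, and 1 lower, Oasl2 by -0.37 (adjusted p = 0.931), and the extracellular matrix list 1 of 29 higher and 7 lower (5 and 5 with library size alone; list adjusted p = 0.494), with the basement membrane genes Col4a2 and Lamb2 down by -1.17 and -0.90. Oasl2 lost its call without the first or second library of either group (adjusted p from 0.144 to 0.247), with DESeq2 (0.0714), its size factors (0.0683), library size alone (0.283), the filter of 1 CPM (0.0515) or without mitochondrially encoded genes (0.0871). With DESeq2 or its size factors the interferon list had 2 higher and 0 lower. Of 82 cytosolic ribosomal protein genes 2 rose and 21 fell (0 and 10 adjusted over the list alone; list adjusted p = 0.0676). Without the third cKO library this list was called lower (adjusted p = 2.43e-07), though with all libraries its adjusted p was 0.978 with an estimated correlation, and with library size alone 6 members were higher and 7 lower. Mitochondrially encoded genes had 5 of 13 higher and 0 lower (adjusted p = 0.116), and were called higher without the third control library (adjusted p = 0.00300) or the first cKO library (0.0481), though with all libraries the adjusted p was 0.940 with an estimated correlation. They took 2.84%, 3.15% and 5.61% of counts in the control libraries and 4.38%, 5.40% and 5.92% in the cKO libraries. Of 13 replication-dependent histone genes 1 rose and 2 fell (adjusted p = 0.802).

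**Figure D3:**
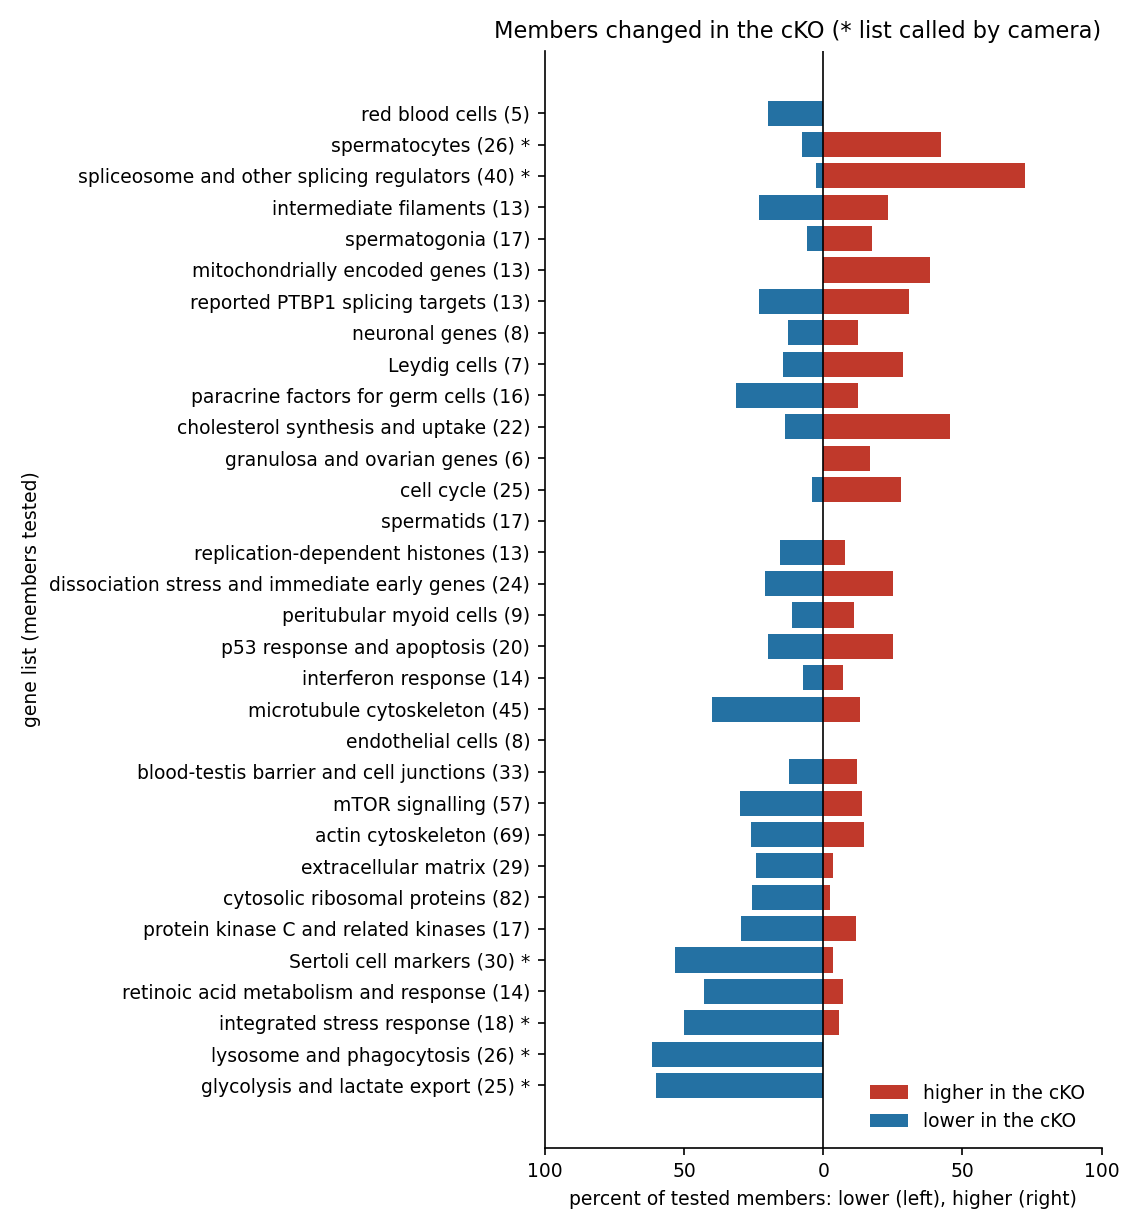
Percent of the tested members of each gene list called lower (left) or higher (right) in the cKO; the lists shown are ordered by median log2 fold, with the number tested in brackets and a star where camera called the list. Splicing regulators had 29 of 40 higher, and glycolysis had 15 of 25 lower; the microtubule, actin, junction, mTOR, extracellular matrix and endothelial medians turn positive with library size alone.

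Camera called 6 of 33 lists, and with an estimated correlation called 0, with 1 at an unadjusted p under 0.05, while fry, which asks whether a list moves one way on balance, called 9. Among the lists given here median, mean and test differed in sign for the junction, paracrine, myoid, endothelial, red blood cell and histone lists. The extracellular matrix and endothelial medians also turned positive with library size alone. Where not given, counts adjusted over the list alone were within 1 gene of those over all genes, in this comparison and in the immunoprecipitate.

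The comparison of the PTBP1 immunoprecipitate with its input asked which transcripts PTBP1 binds in cultured wild-type Sertoli cells. The transcripts of Lpp, Uhmk1 and Tram2 were enriched 5.63-fold, 5.41-fold and 5.45-fold over input. The PTBP family's own transcripts were also higher: Ptbp3 4.37-fold, Ptbp1 2.17-fold and Ptbp2 1.75-fold, the last under the limit for an enriched transcript. Prkca, which encodes PKCα, was 2.09-fold enriched (135 to 282 CPM), and Rictor 2.56-fold. Their exon lengths were 8992 and 9311 bases, and 27.2% of genes over 4 kb were enriched at 2-fold or more. Scaling by library size alone moved the median log2 fold of all genes by -0.36, so an enrichment near 2-fold may not reach that limit. In sorted controls Prkca was at 13.6 CPM. Ribosomal protein and histone transcripts were depleted almost as whole classes: 81 of 82 and 57 of 59 were lower, with median log2 folds of -5.17 and -4.51.

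Of 12854 genes tested, 5527 were higher and 5758 lower in the immunoprecipitate (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 2664 and 3471 by 2-fold or more. The groups did not overlap for 87.9% of genes, where chance gives 10%. Enrichment is relative to other transcripts and no control antibody is among the samples. With library size alone the median log2 fold moved by -0.36, 4207 genes were higher and 7034 lower, and 247 genes called here turned to the opposite call.

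Mmgt1 (5.76-fold), Lpp, Tram2, Uhmk1, the estrogen receptor gene Esr1 (5.32-fold), Kantr (5.30-fold), Slc25a16 (5.26-fold), Slc35a4 (5.26-fold), Tfcp2l1 (5.23-fold) and Hdx (5.12-fold) were the most enriched by the named-gene rule. Lpp rose from 441 ± 12.7 to 2483 ± 69.6 CPM (n = 3; adjusted p = 6.86e-20). The most depleted was Ccnb1ip1, at 9139 ± 632 CPM in the input and 624 times lower in the immunoprecipitate (n = 3; adjusted p = 2.03e-07). It was followed by Rps12, Rpl26, Atp5e, Rpl35, Rps26, the actin-sequestering thymosin gene Tmsb4x, Rpl34, Rpl32 and Rpl17, which were 174, 105, 87.1, 85.7, 84.9, 81.1, 80.7, 80.5 and 80.3 times lower.

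Of 58 mTOR genes 29 were higher and 26 lower, with Eif4ebp2 4.02-fold and Deptor, an mTOR inhibitor, 3.55-fold enriched, and Mtor and Rptor at 0.877 and 0.598 of input. In the protein kinase C list 11 of 16 were higher and 4 lower (5 and 6 with library size alone), with the PKC substrate Marcks at 2.50-fold and Prkcd at 0.355 of input. The actin list had 26 of 69 higher and 39 lower: Tpm1, Pfn1, Arpc1b and Myl6 were at 0.116, 0.114, 0.115 and 0.0725 of input. The microtubule list had 24 of 48 higher and 21 lower, with Tubb6 and Dynll1 at 0.182 and 0.224 of input. Of 14 intermediate filament genes 3 were higher and 10 lower, with Vim at 0.382 of input, and of 35 junction genes 18 were higher and 11 lower, with Cldn12 at 3.24-fold, Cldn11 at 1.76-fold and Gja1 at 1.54-fold. Of 28 Sertoli cell markers 15 were higher and 12 lower: Sox9 and Amh were 1.58-fold and 1.37-fold higher, and Wt1 and Dmrt1 were at 0.488 and 0.300 of input. Amh lost its call with library size alone (adjusted p = 0.353).

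Of 14 reported PTBP1 splicing targets 7 were higher and 7 lower, and of 40 splicing regulators 14 and 22, with Celf2 3.81-fold and Rbfox2 2.64-fold enriched. Cholesterol genes were 13 higher and 9 lower of 23, glycolysis 10 and 13 of 26, lysosome 9 and 14 of 26, retinoic acid 8 and 6 of 15, and paracrine factors 14 and 6 of 21, with Hsd17b7, Stra6 and Igf1 enriched 5.08-fold, 3.71-fold and 3.68-fold. Stress and immediate early genes were 13 higher and 9 lower of 24, integrated stress response 10 and 9 of 21, p53 response 8 and 13 of 21, cell cycle 5 and 13 of 25, interferon 4 and 11 of 19, and extracellular matrix 9 and 16 of 32. Mitochondrially encoded genes were 2 higher and 5 lower of 8. Among markers of other cells the counts were 6 and 3 of 17 for spermatogonia, 2 and 10 of 14 for spermatocytes, 0 and 3 of 3 for spermatids, 5 and 4 of 9 for Leydig cells, 2 and 8 of 11 for myoid cells, 2 and 2 of 5 for macrophages, 0 and 4 of 7 for endothelium, 4 and 5 of 9 for granulosa genes and 9 and 5 of 16 for neuronal genes. The 1 red blood cell gene tested, Alas2, was 1.961-fold higher.

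Camera called 2 of 32 lists, ribosomal proteins (adjusted p = 3.73e-21, and 0.457 with an estimated correlation) and histones (1.86e-11, and 0.971), and the other tested lists had adjusted p from 0.415 to 0.9752. With an estimated correlation 0 lists were called, 1 had an unadjusted p under 0.05, and fry called 27. The median of the Sertoli, junction, microtubule, mTOR, protein kinase C, cholesterol, retinoic acid, spermatogonia, stress and reported target lists turned from positive to negative with library size alone. The members higher and lower were then 9 and 14 for Sertoli, 16 and 17 for junction, 19 and 25 for microtubule, 23 and 31 for mTOR, 9 and 11 for cholesterol, 5 and 8 for retinoic acid, 4 and 6 for spermatogonia, 9 and 12 for stress, 8 and 10 for integrated stress response, 9 and 8 for paracrine and 5 and 6 for neuronal genes. Median and mean differed in sign in the Sertoli, microtubule, mTOR, retinoic acid, Leydig, integrated stress response and reported target lists. Enrichment rose with exon length across genes, which are not independent replicates: the median log2 fold was -3.45 for 333 genes under 1 kb, -1.39 for 1554 of 1 to 2 kb, -0.35 for 4256 of 2 to 4 kb and 0.39 for 6680 over 4 kb (Spearman's correlation 0.428, Pearson's r with log2 length 0.499).

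**Figure D4:**
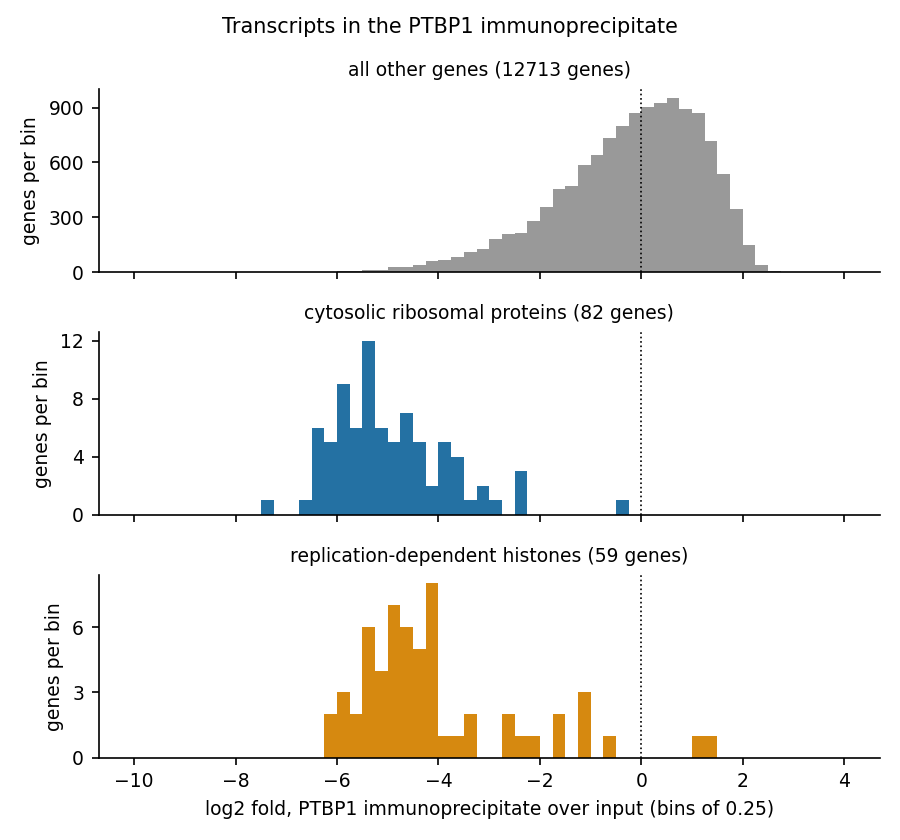
Number of genes per bin of log2 fold in the PTBP1 immunoprecipitate over input, for the ribosomal protein list (82 genes), the histone list (59 genes) and all other genes. The ribosomal protein and histone medians lie at -5.17 and -4.51, and at -5.53 and -4.88 with library size alone.

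The overlap asked whether transcripts enriched with PTBP1 are those that change when Ptbp1 is lost. Enriched transcripts were more often lower in the cKO, 631 of 2267 (27.8%, against 23.5% of other genes), and less often higher, 278 (12.3%, against 19.97%). Among those lower in the cKO were Ptbp1, Chpf, a chondroitin polymerizing enzyme, which fell by 1.51 and was 2.14-fold enriched, the RNA helicase gene Mov10 (1.55 and 2.01-fold), Ttll12 (1.39 and 2.17-fold), Tmem86a (1.24 and 3.17-fold), Tex261 (1.19 and 4.05-fold), Cercam (1.31 and 2.50-fold), Pigt (1.23 and 3.995-fold), the riboflavin transporter Slc52a3 (1.15 and 4.09-fold) and Lrp10 (1.11 and 2.22-fold). Among those higher were Porcn, which modifies Wnt proteins, by 1.504 (3.37-fold enriched), Dazl by 1.39 (2.25-fold), Stard4 by 1.02 (3.34-fold), Tmem47 by 1.64 (3.63-fold), Chordc1 by 0.98 (2.11-fold) and Strbp by 0.91 (2.01-fold). Stag2, Eif1a, Thoc2 and Eea1 rose by 0.82, 0.82, 0.80 and 0.78 and were enriched 2.37-fold, 2.17-fold, 2.14-fold and 2.08-fold.

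Over the 11419 genes tested in both comparisons, the odds ratio was 1.26 for lower genes (95% confidence interval 1.13 to 1.40, Fisher's exact test p = 1.75e-05; 551.5 expected) and 0.560 for higher genes (0.487 to 0.642, p = 1.71e-18; 418.1 expected). Genes are not independent replicates, so these p-values and intervals overstate the certainty. The odds ratios were 1.31 and 0.544 in a logistic regression with both expression levels, and 1.63 and 0.470 with exon length added. The overlap was not recomputed with another scaling, so its dependence on scaling was not tested. Library size alone gave 1863 lower and 3476 higher genes in the cKO and moved the median log2 fold in the immunoprecipitate by -0.36. Without the third cKO library the association with lower genes was lost (odds ratio 1.06, Fisher's exact test p = 0.289). The cells compared also differed in being sorted or cultured, and the libraries in RNA preparation (poly(A) for the sorted cells) and kit. CPM were scaled within each comparison. The myoid gene Acta2 was at 1163 CPM in the input and 57.8 in sorted controls, and Myl9 at 208.3 and 289.6. Endothelial Cdh5 was at 68.1 and 1.14, Amh at 17.049 and 268, and Sox9 at 433 and 419. Whether RNA of other cells in the culture shaped the enrichment was not tested.

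The authors' deposited table of the sorted libraries gave 2358 genes higher and 2147 lower at their adjusted p under 0.05. Of the genes called here, 4194 were called in the authors' deposited table in the same direction, 0 in the opposite direction and 1035 not. The signed fold in the authors' deposited table was -30.8 for Ptbp1, 2.74 for Ptbp2, -1.61 for Rptor and -2.06 for Amh, and -1.15 for Prkca with an adjusted p of 1. Ptbp3, Sox9 and Cldn11, called here, were not called in the authors' deposited table, with signed folds of 1.34, -1.27 and -1.25 and adjusted p of 0.0656, 0.0538 and 0.0822.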

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

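Chosen after the results were seen were the tests of spermatid RNA, of meiotic germ cells, of genes under 600 bases and of scaling, and the counts over other splits; the tests of direct loss of PTBP1 and of matched length were written before their results were known. The written bounds of the matched length test for ribosomal proteins were replaced for a time after its result was seen and then restored. Groups of 3 libraries were too small for a test of single outlying libraries, so no rule for a closer look was applied.

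The spermatocyte list was called higher in the cKO (adjusted p = 1.17e-04, and 0.522 with an estimated correlation) although the cells were sorted from mice with the mTmG reporter, and a gate on that reporter would remove germ cells. All 26 members passed the count filter in these libraries and none is in another list. Spermatid RNA was not seen to rise. The mean log2 fold of 17 spermatid genes was 0.06 with an upper 95% bound of 0.28, and Oaz3 was at 0.956 and 0.815 CPM in control and cKO. That bound was taken over genes of the same libraries, with an estimated correlation of 0.502, so it is too narrow to exclude a small rise. For direct loss of PTBP1, 0 of 8 risen members tested in the immunoprecipitate were enriched at 2-fold or more and 6 were depleted. This met the bound written beforehand against direct loss. But reported PTBP1 splicing targets were themselves 7 higher and 7 lower of 14, and Ptbp2, which rose in the cKO, also fell short of 2-fold. The limit of 2-fold thus cannot decide on direct loss. Tex15 was 1.81-fold higher over input, under that limit, and rose by 1.69 in the cKO. Germ cells in meiotic prophase cannot be told apart from meiotic transcription in the Sertoli cells: of 12 members under 8 CPM in controls 33.3% (4) were called higher and all 12 had log2 folds above 0, while the abundant Ldhc went from 174 to 211 CPM without a call. An effect of the Ptbp1 deletion on either stays open.

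Ribosomal protein and histone transcripts were depleted in the immunoprecipitate. The ribosomal protein median was -5.53 with library size alone. That scaling moves every gene by about the same amount (median -0.36), so this outcome was fixed and is no test of scaling. For histones, of median exon length 474.5 bases, short length is consistent with the depletion: they lay -0.94 from 10 genes each of like length, with 69.0% of 58 below. For ribosomal proteins the same difference was -3.68, with 96.3% of 82 below, which passed the bound set beforehand against length as the whole cause. The exon length pools isoforms, with a median of 1660.5 bases for these genes, so the matched genes may be longer than the transcripts present. Against 47 other genes under 600 bases the difference was -1.70 (95% interval -2.69 to -0.85, from a bootstrap over genes). It lay below 0 but short of the bound written for that test. Length as the whole cause, and its share of the depletion, stay open.

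Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05. The 5229 genes changed in the cKO compare with 0 in the highest other split by edgeR (1 of 10 splits as large; up to 579 genes there at an unadjusted p under 0.05), and the 11285 genes in the immunoprecipitate with 0 (1 of 10; up to 21). For gene lists the cKO gave 6 and the highest other split 11 (8 of 10 as large), and the immunoprecipitate 2 and 4 (10 of 10).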

How the results depend on the processing

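Chosen after seeing the data were the alternatives without mitochondrial genes, without the third library of both sorted groups, and without ribosomal protein and histone genes; the other alternatives were planned. Ptbp1 kept its direction and call in every alternative, and its log2 fold ran from -5.02 to -4.96 as single libraries were left out. The cKO counts moved with library size alone (1863 lower), with 1.5-fold as a further threshold (3140 genes, 1539 higher and 1601 lower) and with 2-fold (860, 550 and 310); 2-fold gave 6135, 2664 and 3471 in the immunoprecipitate. Added thresholds lower counts by construction; the cause of the shift with library size was not tested. Leaving out single libraries gave 3784 to 5660 cKO genes (1717 to 2537 higher, 2067 to 3123 lower), 10997 to 11225 immunoprecipitate genes (5413 to 5507 and 5584 to 5730), 5 to 8 and 2 to 2 lists, and odds ratios of 0.4325 to 0.6982 for higher and 1.059 to 1.465 for lower genes; the lowest, without the third cKO library, had a Fisher's exact test p of 0.289, and the cause was not tested. With an estimated correlation camera called 0 cKO lists and 0 immunoprecipitate lists; fry, which does not compare a list with other genes, called 27 of the latter. Fry gave the direction opposite to camera for the reported PTBP1 targets in the cKO (adjusted p = 0.0174), a list that holds the deleted Ptbp1, so that this direction decides nothing, and in the immunoprecipitate for those targets (2.30e-05), Sertoli markers (7.48e-04), microtubules (2.61e-04), retinoic acid (0.00152), Leydig cells (2.30e-05) and the integrated stress response (0.0267). No paired analysis was made for the sorted libraries: the columns carry no replicate number of the labels, and a block by column order would have inferred the pairs. No pseudocount was varied, since counts were deposited. A replicate block gave 11462 genes in the immunoprecipitate and a block by the first number of the library name 11451; same-numbered inputs and immunoprecipitates had deviations from the group means correlated at 0.116, 0.0403 and 0.175, and not every library correlated best with its own number. Other alternatives kept direction and side of the threshold for 1411 values of named genes in the cKO and 1693 in the immunoprecipitate, while 122 and 28 lost the call, with added thresholds included, and 17 in the cKO gained it. With 1 library left out 64 and 6 lost the call, and 9 in the cKO gained it.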

Other observations

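The tests of YAP and TEAD target genes and the naming of the genes in this part were chosen after the results were seen; the test of terminal oligopyrimidine transcripts was planned before its result was known.

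Ribosomal protein transcripts belong to a class that starts with an oligopyrimidine tract and is controlled by mTOR, and the class as a whole may be depleted with PTBP1. Of 20 members that are not ribosomal proteins 16 lay below genes of like exon length, with a median difference of -1.32 and a median log2 fold of -2.10; Tpt1, Eef1b2 and Naca were at -5.91, -4.93 and -3.79, and Pabpc1 and Eif4b at 0.43 and 0.23. The difference passed the bound set beforehand for a depletion beyond exon length. The exon length pools isoforms (median 2632.5 bases, 7034 for Naca), so a shorter length of the transcripts in these cells stays open beside a depletion of the class.

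Ccn1 and Tnfrsf12a, targets of the YAP and TEAD transcription factors, were among the largest rises in the cKO, and the class might rise with them. Both were highest in the third cKO library: Ccn1 at 325.3 CPM against 89.17 and 158.8, and Tnfrsf12a at 77.88 against 33.55 and 35.64. Of 19 other targets 5 rose and 4 fell, with a mean log2 fold of 0.31 (upper 95% bound 0.71), and camera gave p = 0.551 (0.558 with an estimated correlation). Tgfb2, Ccn2, F3, Fstl1 and Crim1 rose by 2.42, 1.62, 0.93, 0.71 and 0.61, and Axl, Ajuba, Amotl1 and Nuak2 fell by 0.92, 0.85, 0.69 and 0.46. A rise of the class was not shown, and the interval does not exclude it.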
